A study of Mus musculus with 12 samples.

How the data were processed

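Nuclei from 6 frozen mouse livers, 3 of control mice and 3 of mice with hepatocyte loss of the DNA-binding part of TCF7L2, were profiled for RNA and accessible chromatin together, with 1 library pair per liver. The deposited matrices hold raw counts, per the file headers, with 1 row per gene or peak and 1 column per nucleus barcode. Per the submitters' processing notes they were made with Cell Ranger ARC 2.0.2 on the mouse build mm10. Gene rows are UMI counts (unique molecular identifiers, which mark single captured RNA molecules). Peak rows are whole numbers that are even in 78.2% to 79.7% of entries, as when each fragment puts both of its cut ends into a peak. The other deposited values used are the positions of peaks and of transcription start intervals in the feature lists. Gene rows were the same 32285 in all 6 lists, while each library had its own list of 122549 to 134749 peaks, so peaks had been called per library. How nuclei were called, and with which peak caller settings, is stated neither by the labels nor by the headers. Positions are given from 1, on mm10, and a gene's position is its transcription start interval.

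Nuclei were kept with at least 500 UMIs, 300 genes and 1000 peak counts, and at most 5% of UMIs from mitochondrial genes. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 0.06) and left out, which removed 5 to 73 nuclei per library, 0.164% to 2.05% of those passing. Counts were log-normalised, 2000 variable genes were reduced to 30 principal components, and nuclei of all libraries were clustered together with Leiden (leidenalg 0.10.2) at resolution 1 on 15 neighbours, with seed 1. Clusters were named "like" a cell type from marker lists fixed before the data were examined, and a cluster with fewer than 3 detected markers of its type, with leading genes of another type, or with few UMIs and none of its markers in the lead stayed unnamed. Nuclei of hepatocyte clusters that also carried another type's markers were set aside as mixed. This used markers at 10 CPM (UMIs scaled to a library total of 1000000) or less in hepatocyte clusters, and needed at least 5 UMIs of them making up at least 0.02% of a nucleus. The details of the naming and mixed rules were settled over several passes after the clusters had been seen and before any test between genotypes. Unnamed clusters and mixed nuclei together held 24.4% ± 0.575 of control and 25.9% ± 6.51 of mutant nuclei (mean ± SD, n = 3 livers each). They were left out of every comparison except that over all nuclei.

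Raw UMI counts were summed per library over the nuclei of a type and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, R 4.3.3), with livers as replicates and Benjamini-Hochberg (BH) adjustment. A gene, region or list was called where the adjusted p was under 0.05. Log2 fold changes are mutant minus control. CPM values are per library and are given as mean ± SD over 3 livers. Of the other cell types, endothelial-like, macrophage-like and stellate-like nuclei were tested, each with at least 20 nuclei per library. Cholangiocyte-like and T or NK cell-like nuclei also had at least 20 per library but were not tested. For zonation, each hepatocyte-like nucleus got a score, the mean of 12 pericentral genes minus the mean of 12 periportal genes, and nuclei were ranked within their library and divided into 3 equal parts. The pericentral and periportal end parts were summed and compared within livers (library as a block), without the 24 scoring genes. Regions at these genes were kept when accessibility was compared between the ends. A change of zonation is the interaction of position and genotype. For accessibility, overlapping peaks of the 6 libraries were merged into 170050 regions, and the 96422 with a peak in every library were tested. Covered length in the shared regions was 83195586 to 83316694 bp per library, with mean counts per kb of 638, 720 and 601 in controls 1 to 3 and 637, 871 and 702 in mutants 1 to 3. In all, 22 gene lists fixed before the data were examined were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives. Shares of nuclei were compared with exact two-sided permutation tests, for which 3 livers against 3 allow no p below 0.1. For shares of nuclei with a UMI, each nucleus was thinned to 1000 UMIs and shallower nuclei were left out.

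Genes named in the text were picked by a rule fixed before the data were examined. It takes 20 genes of Wnt signalling and zonation in every case, then up to 8 called genes per direction with the largest fold change among those at or above the median level whose groups do not overlap, and then up to 4 members per list by lowest p. Regions take 5 per direction and those called within 100000 bp of the fixed genes, and the other cell types 5 genes each by lowest p. Alternatives fixed in advance were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, the replicate number as a block, each library left out in turn, doublets kept, a minimum of 1000 UMIs, all kept nuclei, 4 parts of the ranking in place of 3, other scoring genes, other region definitions and other depths of thinning. Alternatives chosen after the data had been seen were mixed nuclei kept, nuclei above 100000 UMIs left out, unnamed nuclei left out, peak counts read as fragments, and zonation within mutants from the periportal scoring genes alone. The tests of changed genes per cell type, gene zonation in controls, changed gene zonation and changed regions were tested on simulated data. These data were made from the real libraries' means and depths with seeded changes. The tests over all nuclei, of zonation within mutants and of zonation of regions had no such check. In the hepatocyte comparison (14549 simulated genes) edgeR recovered 0% of 1.5-fold, 8% of 2-fold, 78.7% of 4-fold and 93.5% of 8-fold changes, with 6 false calls among 90. In the test of zonation in controls (12491 genes) it recovered 53.1% of 1.5-fold and 85.7% of 2-fold differences, with 21 false calls among 186. In the accessibility test (93100 regions) it recovered 12% of 1.5-fold, 40.8% of 2-fold and 98% of 4-fold changes, with 16 false calls among 140. A planned test of TCF/LEF motifs was left out because no genome sequence was at hand. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9 were used.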

Results

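Livers of 6 mice were profiled by single-nucleus multiome sequencing, which reads nuclear RNA and transposase-accessible chromatin from the same nuclei. The 3 control mice carried loxP sites around exon 11 of Tcf7l2, a stretch that codes for a piece of the DNA-binding domain of TCF7L2, the transcription factor at the end of Wnt signalling. The 3 littermate mutants also carried Albumin-Cre, which removes the floxed stretch in hepatocytes. The series asks how metabolic zonation, the graded division of work among hepatocytes between portal tract and central vein, depends on TCF7L2. Livers were handled in control and mutant pairs on 3 consecutive days, and the diet of these 6 mice is not stated. About 5000 nuclei were used per mouse, per the labels, and the files held 3059, 3442 and 3167 barcodes for controls 1 to 3 and 3432, 3952 and 4037 for mutants 1 to 3. After filtering, the controls kept 2674, 3042 and 2357 nuclei with 41518358, 47430417 and 21032222 UMIs, and the mutants 2813, 3555 and 3491 nuclei with 35660605, 59055956 and 59233595 UMIs. Peak counts in kept nuclei were 98331437, 110340896 and 85089614 in the controls and 106146313, 121976277 and 130801011 in the mutants.

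Hepatocyte-like nuclei were the largest class, with 9019 nuclei, and made up 50.8% ± 0.575 of control and 49.7% ± 5.06 of mutant nuclei (SD, n = 3 livers each, exact permutation p = 1). Stellate-like nuclei made up 10.9% ± 0.778 and 11.7% ± 1.66 (exact p = 0.6), and endothelial-like nuclei 5.92% ± 1.14 and 5.51% ± 1.54 (exact p = 0.7). Macrophage-like nuclei made up 2.93% ± 0.531 of controls and 1.91% ± 0.595 of mutants (exact p = 0.2). T or NK cell-like nuclei made up 1.33% ± 0.471 and 0.909% ± 0.174 (exact p = 0.2), B cell-like nuclei 1.02% ± 0.447 and 0.947% ± 0.0476 (exact p = 1), and cholangiocyte-like nuclei 2.32% ± 0.876 and 2.96% ± 1.17 (exact p = 0.5). Mesothelial-like and dendritic cell-like nuclei were under 1% in every library (exact p = 0.7 and 1). With 3 livers against 3 no p can be below 0.1, and every value was 1 after BH adjustment over the types. Nuclei in hepatocyte clusters, mixed ones included, parted both by genotype and by liver. Clusters 0, 2 and 4 held 84.3%, 91.0% and 58.8% of these nuclei of mutants 1 to 3 and 0.0674%, 1.90% and 12.5% of those of controls 1 to 3. Clusters 1, 5, 6, 7, 8 and 10 held 95.7%, 97.0% and 80.1% of the controls' and 6.33%, 2.28% and 38.5% of the mutants'. Several of these clusters came mostly from 1 liver. Control 1 gave 711 of 719 nuclei in cluster 5 and 667 of 673 in cluster 7, control 2 gave 469 of 482 in cluster 10, control 3 gave 538 of 654 in cluster 8, and mutant 3 gave 851 of 1007 in cluster 4. Cluster 1 held 778 nuclei of control 2 and 624 of mutant 3.

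Tcf7l2 itself (ENSMUSG00000024985, mm10 chromosome 19, transcription starts 55741820–55895510) was read in hepatocyte-like nuclei of every liver. Its level was 466, 660 and 567 CPM in controls 1 to 3 and 757, 869 and 757 CPM in mutants 1 to 3 (564 ± 96.9 against 794 ± 64.4, n = 3 each, log2 fold change 0.45, edgeR adjusted p = 0.852). Counts per gene from the 3′ ends of transcripts do not single out exon 11, so these levels check neither the deletion nor the labels. Endothelial-like nuclei, in which Albumin-Cre should be silent, had 163 CPM in controls and 223 CPM in mutants. The hepatocyte profile made up an estimated 24.3% to 49.5% of their UMIs in controls and 13.8% to 28.2% in mutants. Hepatocyte Tcf7l2 RNA may thus make up part of these levels. Within the gene, 2 regions had a called peak in all 3 controls and in no mutant (chromosome 19, 55792533–55793358 and 55890381–55891077), a pattern shared by 635 regions across the genome. They were picked after the peak lists had been seen, and where exon 11 lies is not given in the files.

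Mutant hepatocyte-like nuclei had far less of some transcripts that mark the hepatocytes around the central vein. Slc1a2, a glutamate transporter (ENSMUSG00000005089, chromosome 2, 102658659–102706438), averaged 345 ± 30.4 CPM in controls and 0.157 ± 0.0554 CPM in mutants (log2 fold change −11.07, edgeR adjusted p = 4.1e-06). Glul, the glutamine synthetase that clears ammonia (ENSMUSG00000026473, chromosome 1, 153899944–153900585), fell from 204 ± 33.0 to 9.16 ± 2.61 CPM (log2 fold change −4.52, edgeR adjusted p = 0.000139). Lgr5, the R-spondin receptor (ENSMUSG00000020140, chromosome 10, 115587493–115587780), fell from 116 ± 65.3 to 0.853 ± 0.251 CPM (log2 fold change −7.12, edgeR adjusted p = 0.00152). Oat, ornithine aminotransferase (ENSMUSG00000030934, chromosome 7, 132576398), fell from 144 ± 99.7 to 2.60 ± 0.670 CPM (log2 fold change −5.80, edgeR adjusted p = 0.0146). Axin2, a feedback target of Wnt signalling (ENSMUSG00000000142, chromosome 11, 108920349–108923181), fell from 18.4 ± 9.43 to 2.70 ± 0.168 CPM (log2 fold change −2.79, edgeR adjusted p = 0.0146). Rising genes were fewer. Nebl, an actin-binding protein, went from 9.98 ± 1.86 to 41.0 ± 6.79 CPM, and Med12l, a relative of a Mediator subunit, from 26.0 ± 5.34 to 97.7 ± 9.05 CPM. Srgap3, a Rho GTPase-activating protein, rose from 19.5 ± 2.06 to 56.7 ± 8.54 CPM, and Pgm3, an enzyme of UDP-GlcNAc synthesis, from 41.8 ± 7.08 to 94.2 ± 10.7 CPM (edgeR adjusted p from 0.00486 to 0.0437 over these 4 genes).

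Of 14830 genes tested with edgeR's quasi-likelihood test and BH adjustment, 60 fell (log2 fold change −1.24 to −11.07) and 8 rose (1.14 to 4.29) in mutant hepatocyte-like nuclei. In each of the 68 the 3 mutants lay beyond the 3 controls. Over all tested genes the groups did not overlap in 10.4%, where chance gives 10%, and 902 genes had an unadjusted p under 0.05. Other falling genes were Cyp2a5, a coumarin hydroxylase (28.8 ± 5.18 to 0.0806 ± 0.0478 CPM), the organic cation transporter Slc22a3 (30.9 ± 19.5 to 0.871 ± 0.269 CPM), the dicarboxylate transporter Slc13a3 (4.38 ± 0.761 to 0.0550 ± 0.0306 CPM), the long noncoding gene model Gm13481 (44.4 ± 5.89 to 0.410 ± 0.165 CPM), and the major urinary proteins Mup11 (128 ± 43.8 to 1.69 ± 2.03 CPM) and Mup17 (28.7 ± 18.98 to 0.528 ± 0.418 CPM). Mup genes, Cyp2a5 and Cyp2c38 have near-identical relatives, so how their reads were split between copies is uncertain. Genes not called included Tcf7l1, another member of the TCF family (149 ± 8.17 and 293 ± 43.1 CPM, edgeR adjusted p = 0.104), Tcf7 (2.34 ± 0.452 and 0.257 ± 0.221 CPM, edgeR adjusted p = 0.0724) and Lef1 (0.498 ± 0.0828 and 0.250 ± 0.244 CPM). Also not called were Ctnnb1, which encodes β-catenin (60.8 ± 6.33 and 63.0 ± 13.2 CPM), and Hnf4a, a master regulator of hepatocyte identity (457 ± 62.5 and 314 ± 38.1 CPM, edgeR adjusted p = 0.523). Cyp2e1, Rnf43, Tbx3 and the bile acid enzymes Cyp7a1 and Cyp27a1 were not called (log2 fold changes −1.49, −0.52, −1.31, 0.24 and −0.45), nor were the periportal Cyp2f2, Hal and Pck1 (0.39, −0.12 and −0.67). Signs of some of these small changes hung on 1 library. Cyp7a1 was at −0.29 without control 1 and −0.87 without mutant 2, Hal at 0.03 without control 2, 0.04 without mutant 2 and 0.12 without mutant 3, and Ctnnb1 at −0.01, −0.08 and −0.15 without control 2, control 3 and mutant 3. Over all kept nuclei, whatever their type, 5 genes rose and 37 fell of 17657 tested, and 41 of the 68 hepatocyte calls were among them.

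Leaving out 1 library moved the count of hepatocyte calls from 68 to 43 without control 1, 45 without control 2, 24 without mutant 1, 30 without mutant 2 and 33 without mutant 3. Over all nuclei the count moved from 42 to 24 without control 1, 17 without mutant 1, 22 without mutant 2 and 24 without mutant 3. Of the 68 hepatocyte calls, 17 were kept in all 6 of the fits that left out 1 library. Among them were Slc1a2, Glul, Lgr5, Cyp2a5, Gm13481, Slc13a3, Nebl and Med12l. Axin2 lost its call without mutant 1, 2 or 3 (edgeR adjusted p = 0.104, 0.0745 and 0.0754), as did Oat (0.109, 0.0745 and 0.0833). Cyp1a2, which fell from 15.6 ± 7.14 to 2.97 ± 0.762 CPM, lost it without control 1 or mutant 1, 2 or 3 (edgeR adjusted p = 0.0733, 0.112, 0.123 and 0.138). Mup11 lost it without control 2, mutant 1 or mutant 3 (edgeR adjusted p = 0.0553, 0.111 and 0.0654), Mup17 without mutant 2 or 3 (0.0745 and 0.0712), and Slc22a3 and Srgap3 without mutant 1 (0.0521 and 0.0572). The call of Pgm3 ended without any 1 of the 6 libraries (edgeR adjusted p = 0.0640 to 0.164). Calls gained in single fits were Tcf7 without mutant 3 (edgeR adjusted p = 0.0423), Cyp2c38, Saa4 and Cdh1 without control 1 (0.0367, 0.0367 and 0.0347), Msmo1 without control 2 (0.0346), and Cyp4a10 and Il1r1 without control 3 (0.0318 and 0.0201).

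**Figure D1:**
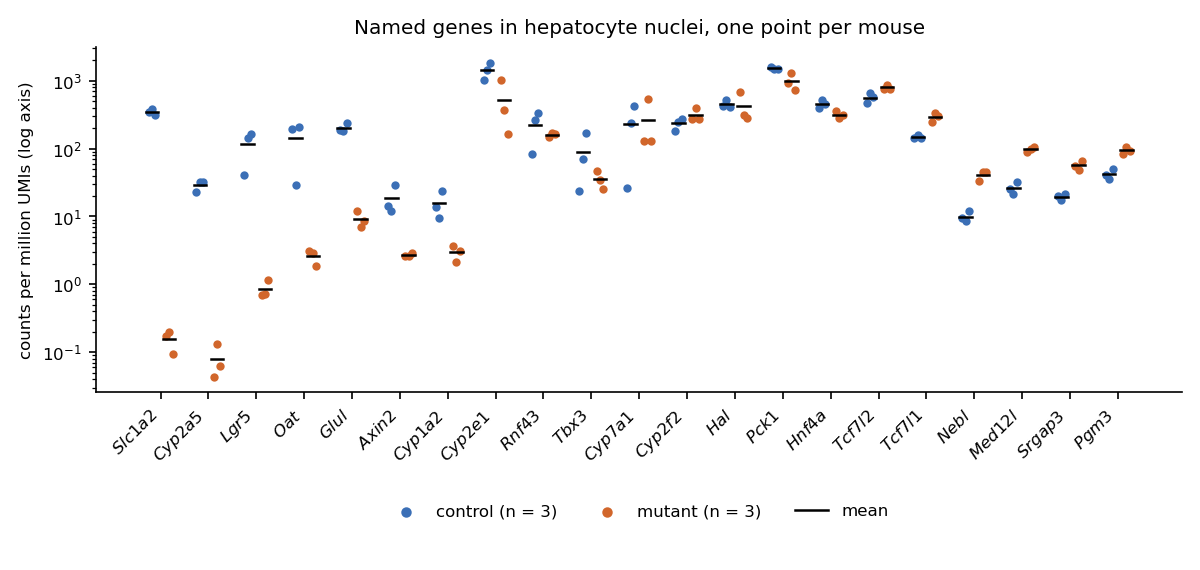
Levels of named genes in hepatocyte-like nuclei, in CPM on a log axis, with 1 point per liver for the 3 controls and 3 mutants. Slc1a2 lay at 345 ± 30.4 CPM in controls and 0.157 ± 0.0554 CPM in mutants (mean ± SD), and Tcf7l2 at 564 ± 96.9 and 794 ± 64.4 CPM.

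The fixed gene lists placed these changes in the pericentral and Wnt programmes and in ammonia handling. Of 45 pericentral genes 11 fell and none rose (camera adjusted p = 9.3e-59), with 19 falling when adjusted over the list alone, and the list's median log2 fold change was −0.83. Of 26 Wnt and TCF targets 6 fell (Slc1a2, Glul, Lgr5, Axin2, Notum, an enzyme that inactivates Wnt proteins, and Tnfrsf19, from 8.35 ± 4.91 to 0.359 ± 0.04999 CPM), and adjusted over the list alone 11 fell and 2 rose, among the latter Tcf7l1 (camera adjusted p = 9.13e-39). The call of Tnfrsf19 ended without mutant 1 (edgeR adjusted p = 0.0572). Of 26 genes of glutamine, ammonia and the urea cycle 3 fell, namely Slc1a2, Glul and Oat, with 6 adjusted over the list alone (camera adjusted p = 5.1e-35). The lists share members: Slc1a2, Glul and Oat are also in the pericentral list, as are Slc1a2, Glul, Lgr5 and Axin2 of the Wnt list. In simulated data with only the pericentral list shifted, 2 other lists were called, and 0 of those without shared members. The simulated genes varied independently, so these data cannot show how many calls correlation between real genes adds. With the 6 livers split into other groups of 3, up to 11 lists were called, against 13 for the real split. Rhbg, an ammonia transporter, was at 0.993 ± 0.584 and 0.0692 ± 0.0539 CPM (edgeR adjusted p = 0.0622). Of 24 male-biased liver genes 1 fell, Mup7, from 35.2 ± 13.5 to 3.54 ± 1.14 CPM (5 adjusted over the list alone, camera adjusted p = 2.92e-05), and its call ended without mutant 2 (edgeR adjusted p = 0.0514). None of 25 acute phase and inflammation genes passed in edgeR with all 6 libraries (Saa4 did without control 1 and Il1r1 without control 3). In that list 20 had fold changes below 0, and adjusted over the list alone 1 rose and 1 fell, the chemokine Cxcl10 (0.0655 ± 0.0291 and 0.839 ± 0.410 CPM) and Steap4 (36.3 ± 6.71 and 16.8 ± 3.71 CPM); the list was lower by camera (adjusted p = 0.000115). With an estimated correlation between genes these 5 lists stayed called, with camera adjusted p = 0.0249, 0.0184, 0.0184, 0.041 and 0.0430 in the order given.

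Another 8 lists were called lower with camera's preset correlation and lost the call with an estimated one. Cholesterol synthesis genes were below 0 in 24 of 25 cases (median log2 fold change −0.57), with Insig1 at 23.6 ± 8.34 and 9.55 ± 4.68 CPM and Sqle at 4.63 ± 2.96 and 1.18 ± 0.907 CPM, and none passed on its own except Msmo1 without control 2 (camera adjusted p = 3.2e-07, adjusted p = 0.299 with an estimated correlation). Fatty acid oxidation and PPARA targets had 0 of 30 genes called (Cyp4a10 without control 3) and 2 adjusted over the list alone, Cyp4a10 (603 ± 124 and 241 ± 37.1 CPM) and the fatty acid transporter Cd36 (67.1 ± 27.2 and 9.10 ± 6.03 CPM), with camera adjusted p = 0.000773 and adjusted p = 0.419 with an estimated correlation. Of 50 xenobiotic metabolism genes 2 fell, Cyp2a5 and Cyp1a2, and 6 adjusted over the list alone (camera adjusted p = 0.000856, adjusted p = 0.473 with an estimated correlation). Gluconeogenesis genes (0 of 27 called, camera adjusted p = 0.000856), immediate early genes (0 of 18, 0.00447), periportal genes (0 of 40, with Cdh1 called without control 1, 0.00958) and clock genes (0 of 22, with Tef, Nr1d2 and Dbp falling when adjusted over the list alone, 0.0249) each had adjusted p = 0.299 with an estimated correlation. Female-biased genes had 0 of 14 called and Cyp4a10 alone adjusted over the list (camera adjusted p = 0.0116, adjusted p = 0.335 with an estimated correlation). Control 1 stood apart from the other controls in several of these lists. It had 656 CPM of Sds against 160 and 180 in controls 2 and 3, and 1803 of Tat against 871 and 658. It also had 744 of Ppargc1a against 136 and 101, 789 of Lpin1 against 224 and 41.5, and 105 of Egr1 against 4.48 and 10.3, but 26.5 of Cyp7a1 against 235 and 422. Calls ended without control 1 for immediate early (camera adjusted p = 0.396), clock (0.357), periportal (0.0630) and fatty acid oxidation genes (0.0630). Without control 2 they ended for xenobiotic (camera adjusted p = 0.110) and female-biased genes (0.564). Without mutant 2 they ended for clock (camera adjusted p = 0.259), immediate early (0.0506) and fatty acid oxidation genes (0.0854), and without mutant 3 for xenobiotic (camera adjusted p = 0.490), female-biased (0.398) and periportal genes (0.177).

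The remaining 9 lists were not called. All lists were tested in hepatocyte-like nuclei alone, so they do not cover these programmes in other cell types. Of 25 listed fibrosis genes 10 were tested, without Col1a1 and Acta2. Of 22 endothelial Wnt genes 12 were tested, without Wnt2 and Wnt9b, and of 24 proliferation genes 15, without Mki67 and Top2a. Of 28 bile acid genes 1 fell, the exporter Abcc4, from 4.95 ± 0.714 to 0.531 ± 0.259 CPM (camera adjusted p = 0.402 for the list). Its call ended without control 2, mutant 2 or mutant 3 (edgeR adjusted p = 0.0540, 0.0745 and 0.0712). None of the measured genes passed in edgeR among 22 of fatty acid synthesis (camera adjusted p = 0.517), 28 of lipid transport (0.218), 27 hepatocyte transcription factors (0.734), 15 of the interferon response (0.961), 10 of fibrosis (0.588), 12 endothelial Wnt genes (0.609), 20 of ER and oxidative stress (0.127, with Herpud1 falling when adjusted over the list alone) and 15 of proliferation (0.771). The median log2 fold change and the test differed in sign for fibrosis (median −0.01, test up) and proliferation (median −0.07, test up), and the mean and the test for fatty acid synthesis (mean −0.04, test up). Single libraries decided some of these. Without control 1 the lists of bile acids (camera adjusted p = 0.0474), fatty acid synthesis (0.0369) and ER stress (0.00862) passed, without control 2 lipid transport (0.0205) and interferon (0.00911), and without mutant 1 bile acids (0.0240), lipid transport (0.0240) and ER stress (0.000759).

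Slc1a2, Lgr5 and Axin2 were each seen in a smaller share of hepatocyte-like nuclei in every mutant than in any control. With every nucleus thinned to 1000 UMIs, Slc1a2 was seen in 13.8% ± 1.95 of control and 0.0177% ± 0.00873 of mutant hepatocyte-like nuclei, and Lgr5 in 8.23% ± 4.22 and 0.0546% ± 0.00414 (n = 3 livers each, exact permutation p = 0.1 for each, BH-adjusted 0.12). In endothelial-like nuclei, which should lack both, the shares were 1.98% and 0.147% in controls and 0% in mutants. Axin2 was seen in 1.72% ± 0.841 and 0.275% ± 0.00812 of hepatocyte-like nuclei, with 1.08% and 0.123% in endothelial-like nuclei (exact p = 0.1). Glul (10.0% ± 0.925 and 0.917% ± 0.240) and Oat (11.4% ± 7.61 and 0.325% ± 0.0775) were no more frequent in hepatocyte-like than in endothelial-like nuclei of the same group (15.1% and 4.69%, 12.2% and 1.18%). Endothelial-like nuclei held more Glul than the hepatocyte profile predicts for stray RNA, with 162 UMIs against 66.6 in controls and 58 against 2.35 in mutants. The hepatocyte transcripts Mup7 and Mup11 exceeded it too, by 10.7 and 8.75 times in controls (Glul 2.43) and 16.5 and 10.7 times in mutants (Glul 24.7). The excess thus does not settle the source of endothelial Glul, and whether these nuclei give a background for it stays open. For Oat the source of the endothelial UMIs was not tested. Cyp2e1 was seen in 48.1% ± 5.93 and 29.4% ± 15.95 (exact p = 0.3), with 41.1% and 9.32% in endothelial-like nuclei. Unthinned shares were 21.5% and 0.298% for Slc1a2, 27.0% and 0.817% for Lgr5, 19.2% and 4.92% for Axin2, 29.1% and 12.3% for Glul, 45.5% and 4.33% for Oat, and 78.6% and 68.6% for Cyp2e1. Median UMIs were 16286, 17021 and 10200 per hepatocyte-like nucleus of controls 1 to 3, 16221, 21827 and 15661 in mutants 1 to 3, and 1988, 2246.5, 1124.5, 1754.5, 1659 and 2216 per endothelial-like nucleus in the same order. Nuclei deep enough to thin numbered 1333, 1525, 1182, 1297, 1961 and 1614 of the hepatocyte-like and 135, 204, 67, 162, 179 and 121 of the endothelial-like nuclei.

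In control livers the lobule axis was recovered from the nuclei themselves, which answers where Tcf7l2 and its relatives are transcribed. Tcf7l2 was somewhat higher at the periportal end (671 ± 101 CPM) than at the pericentral end (462 ± 84.9 CPM, n = 3 livers, log2 pericentral minus periportal −0.58, edgeR adjusted p = 0.000175). Tcf7l1 was mostly periportal, at 290 ± 16.8 against 17.6 ± 1.65 CPM (log2 −4.06, edgeR adjusted p = 3.48e-09). Several other genes of the Wnt pathway were higher at the pericentral end, with Lgr5 at 302 ± 168 CPM pericentral and 0.693 ± 0.167 CPM periportal, Axin2 at 39.0 ± 16.3 and 1.73 ± 1.45 CPM, Tbx3 at 177 ± 143 and 3.90 ± 3.96 CPM, Rnf43 at 376 ± 205 and 84.3 ± 37.7 CPM, and Tcf7 at 4.76 ± 0.887 and 0.583 ± 0.401 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 419 ± 333 CPM pericentral and 10.4 ± 9.92 CPM periportal. Of 12766 genes tested, 1374 were higher at the pericentral and 1534 at the periportal end by edgeR's quasi-likelihood test with BH adjustment. The steepest pericentral genes included Cyp2c38 (log2 9.16), the fatty acid regulator Pparg (7.59), the transcription factor Tox (7.45), the kinesin Kif26b (7.18) and Airn (7.05), an antisense RNA whose reads cannot be told from its partner's if strand was not used. The steepest periportal genes included Cryl1 (−5.27), the muscarinic receptor Chrm3 (−5.19), the glutamate receptor Grm8 (−4.97), Sult5a1 (−4.70), which the pericentral list had held, the semaphorin receptor Plxna2 (−4.40) and Ncam2 (−4.25). Hnf4a was slightly periportal (log2 −0.29, edgeR adjusted p = 0.0114), a call that ended without control 1 (0.0712) or control 3 (0.0738), and Ctnnb1 was not zonated (−0.03).

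Pathways sorted along the axis in controls as well. Of the 33 pericentral and 27 periportal list genes left after the scoring genes, 31 and 23 were higher at the end their list names. Xenobiotic metabolism leaned pericentral (27 of 45 genes, with 6 periportal), as did fatty acid oxidation (12 of 30, with 4). Cholesterol synthesis (19 of 25 genes, 0 pericentral), fatty acid synthesis (11 of 22, 0 pericentral), gluconeogenesis (14 of 25, with 4 pericentral), the clock (13 of 22, with 2) and acute phase genes (12 of 25, with 5) leaned periportal. All of these counts are from edgeR's quasi-likelihood test with BH adjustment. Wnt and TCF targets split into 13 pericentral and 4 periportal of 22, bile acid genes into 10 and 8 of 26, and genes of ammonia and the urea cycle into 5 and 7 of 19.

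**Figure D2:**
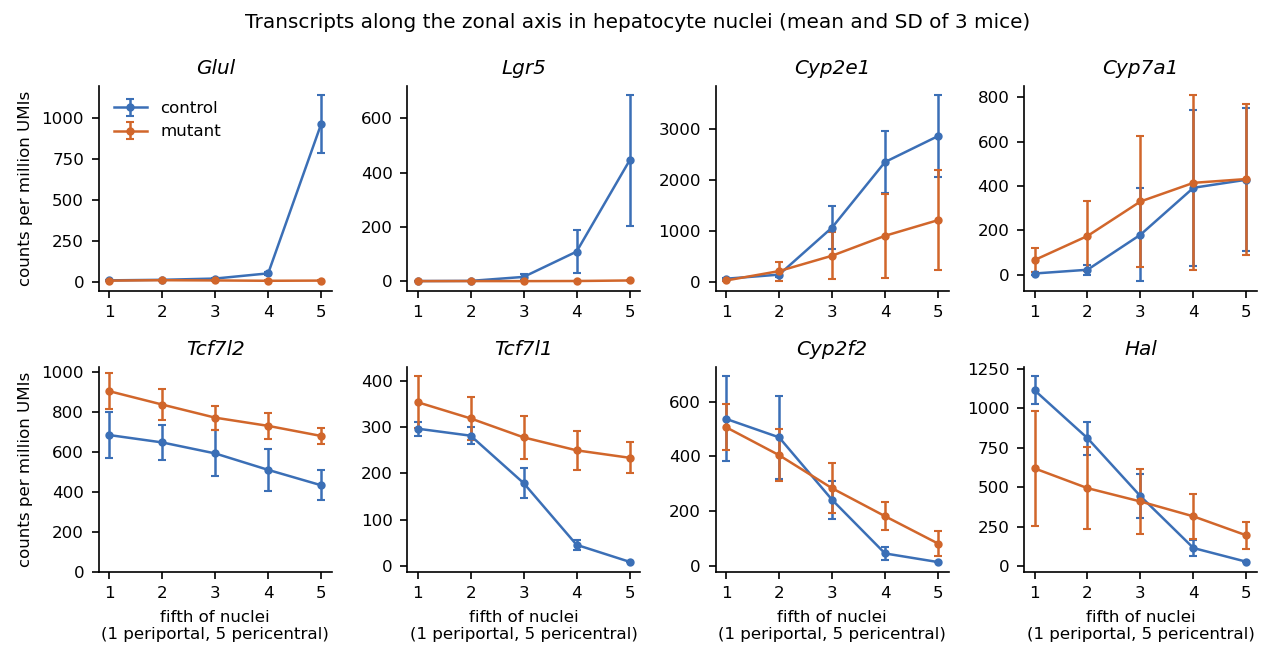
Levels of 8 genes, in CPM, over 5 equal parts of the hepatocyte-like nuclei ranked from the periportal to the pericentral end within each liver. Lines give the mean and SD of the 3 controls and of the 3 mutants. Glul, Cyp2e1, Cyp2f2 and Hal are scoring genes, and Tcf7l1 ran from 297 ± 14.9 CPM in the first to 8.73 ± 1.25 CPM in the last part in controls and from 354 ± 55.8 to 234 ± 33.2 CPM in mutants (mean ± SD).

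Along the ranking of mutant nuclei, which rests on scoring genes of which some had fallen, many genes of both ends differed less. Tcf7l1 reached 240 ± 35.2 CPM at the pericentral end and 344 ± 53.3 CPM at the periportal end (log2 −0.52 in mutants against −4.06 in controls, interaction 3.55, edgeR adjusted p = 5.87e-09). Tox was at 895 ± 107 CPM pericentral and 571 ± 160 CPM periportal, where controls had 1569 ± 335 and 8.81 ± 3.57 CPM (interaction −6.77, edgeR adjusted p = 9e-09). Plxna2 went from 13.3 ± 2.89 to 132 ± 24.7 CPM at the pericentral end and from 272 ± 55.8 to 219 ± 7.42 CPM at the periportal end. Lgr5 (log2 8.61 in controls, 2.18 in mutants), Axin2 (4.58 and 0.63), Rnf43 (2.06 and 0.17), Tbx3 (5.57 and 2.29) and Cyp7a1 (5.42 and 2.09) all had smaller pericentral leads in mutants, each called as an interaction by edgeR (adjusted p from 5.05e-07 to 0.000394). Some genes kept a gradient, such as Chrm3 (−5.19 and −4.07) and Cryl1 (−5.27 and −3.35). Abcd2, a peroxisomal fatty acid transporter, turned from −1.59 to 0.83. Tcf7l2 was −0.58 in controls and −0.33 in mutants, and this interaction (0.26, edgeR adjusted p = 0.0394) was lost with DESeq2 (0.158) and without control 1 (0.1001), control 3 (0.0702), mutant 1 (0.140), mutant 2 (0.109) or mutant 3 (0.116).

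Of 13347 genes, 900 had a higher and 723 a lower pericentral minus periportal difference in mutants by the edgeR interaction test with BH adjustment. With no filter on low counts 923 were higher and 1156 lower of 24831, so which direction held more genes hung on the filter. Among 2801 genes zonated in controls and tested in mutants, 96.8% had a smaller difference there, 2090 kept its sign, and the interaction was called for 1407, of which 1400 went toward 0. Genes picked for a difference in controls tend to have a smaller one elsewhere, so the reverse choice was added after these values had been seen. Of 1127 genes zonated in mutants and tested in controls, 65.0% had the smaller difference in mutants, with medians of 0.57 in controls and 0.45 in mutants in the mutants' direction. The median difference of 1284 genes pericentral in controls was 0.63 in controls and 0.12 in mutants, and that of 1517 periportal genes −0.62 and −0.12. Of the list genes, 26 of 33 pericentral genes changed toward the periportal end and 17 of 27 periportal genes toward the pericentral end. Cholesterol synthesis (16 of 25 genes) moved up and xenobiotic metabolism mostly down (24 of 45, with 5 up). The mutants' ranking itself separated nuclei less. The scores of pericentral and periportal scoring genes correlated across nuclei with −0.792 ± 0.0330 in controls and −0.265 ± 0.0387 in mutants (n = 3 livers each, exact permutation p = 0.1). Median UMIs per nucleus at the pericentral and periportal ends were 20005.5 and 14227, 20135.5 and 13675, and 11305 and 8932 in controls 1 to 3, but 12279 and 18479.5, 17171 and 23915, and 12065 and 19269 in mutants 1 to 3.

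**Figure D3:**
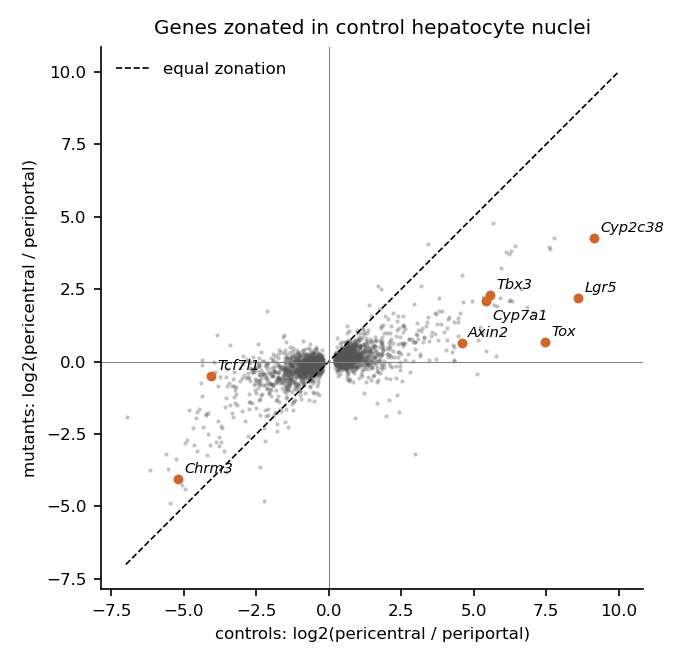
Log2 pericentral minus periportal difference of each gene zonated in controls, in 3 control livers (horizontal) and 3 mutant livers (vertical). These genes were picked in controls, and their points lie nearer 0 in mutants, with median differences of 0.12 for pericentral and −0.12 for periportal genes against 0.63 and −0.62 in controls.

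**Figure D4:**
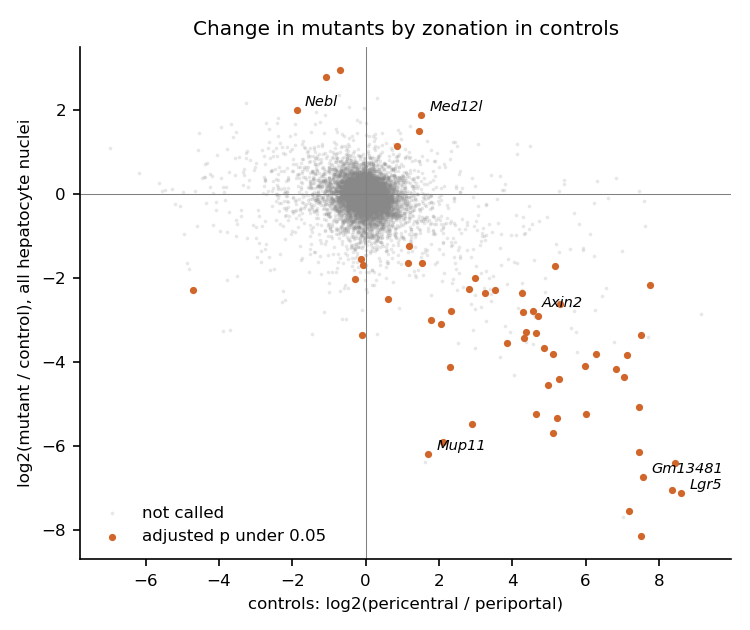
Log2 fold change, mutant minus control, of each gene in hepatocyte-like nuclei (vertical) against its log2 pericentral minus periportal difference in 3 control livers (horizontal). Called genes are marked in colour, and 48 of the 53 falling ones were higher at the pericentral end in controls.

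Genes that fell in mutants were nearly all pericentral in controls. Among 12753 genes tested for both, 48 of the 53 falling genes were higher at the pericentral end in controls, where independent lists would share 5.69 (Fisher's exact p = 2.31e-41), with Abcc4, Axin2, Lgr5, Mup11, Notum, Slc13a3 and Tnfrsf19 among them. Both comparisons use the same control livers, so part of the excess may come from the shared controls. In a count added after the overlap had been seen, over all genes at an unadjusted p under 0.05, 45.7% of 505 falling genes were pericentral. In 20 simulations of unchanged mutants against the same controls the share was 7.32% to 28.0%, of 39 to 61 falling genes each. Simulated mutants were drawn around the observed control means, so deviations of the controls could not enter. These simulations therefore cannot tell how much of the excess comes from the shared controls. The rising genes Med12l, Pgm3 and Srgap3 were also higher at the pericentral end in controls (3 of 6 rising genes), while Nebl was higher at the periportal end.

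Chromatin of mutant hepatocyte-like nuclei was less accessible near some of the falling genes and at other places. A region 337 bp from the transcription start interval of Lgr5 (chromosome 10, 115586236–115587155) went from 15.98 ± 3.71 to 1.91 ± 0.109 CPM (n = 3 each, log2 fold change −3.07, edgeR adjusted p = 0.000308). The region that spans this interval (115587169–115588076) went from 6.78 ± 1.92 to 1.59 ± 0.218 CPM (log2 −2.09). Regions near Sema3f (chromosome 9, 107694286–107695236, 16.6 ± 6.37 to 1.67 ± 0.0996) and Phldb2 (chromosome 16, 45809932–45810826, 14.7 ± 2.18 to 1.96 ± 0.228) fell, as did regions at Slc1a2 (chromosome 2, 102685383–102686472, log2 −2.21), Lef1 (chromosome 3, 131105692–131106690, −1.99), Axin2 (chromosome 11, 108890860–108891915 and 108896777–108897773, −1.41 and −1.48) and the start of Oat (chromosome 7, 132575896–132576750, −1.15). The region with the lowest p among the named rising ones lay 10260 bp upstream of Alb, the gene whose promoter drives Cre here (chromosome 5, 90449730–90450636). It went from 24.5 ± 0.940 to 62.6 ± 11.0 CPM (log2 1.34, edgeR adjusted p = 0.0011), and the Alb promoter region (90460335–90461255), named after its value had been seen, from 31.6 ± 2.48 to 54.8 ± 3.57 (log2 0.79, edgeR adjusted p = 0.00415). The other rising regions named by the fixed rule were at Etl4 (chromosome 2, 20445196–20446131, 4.19 ± 1.23 to 13.7 ± 0.913), near Tspan5 (chromosome 3, 138888957–138889884, log2 1.45), near Schip1 (chromosome 3, 68607059–68607990, 1.36) and near Mboat1 (chromosome 13, 30234743–30235718, 1.30). Falling regions of that rule also lay near Gm3646 (chromosome 1, 39812825–39813705, −2.71) and Tha1 (chromosome 11, 117914166–117915152, −2.70).

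Of 93880 regions tested with edgeR's quasi-likelihood test and BH adjustment, 310 fell and 67 rose, 60 of the falling ones within 1000 bp of a transcription start. Of the 60 falling genes 26 had a falling region within 100000 bp, 42 regions in all where 2.43 would be shared by chance, and of the 8 rising genes 3 had a rising region there. Without 1 library the count of 377 was 132 (control 1), 111 (control 2), 103 (mutant 1) and 149 (mutant 3). When regions needed a peak in only 1 library per group, edgeR called 0 of 121818, with 6237 at an unadjusted p under 0.05 and a lowest adjusted p of 0.219. In this setting a library without a called peak in a region counts as 0 there, whatever its accessibility. DESeq2, run on the 93880 regions alone, called 1717. The calls at Lgr5, Sema3f, Phldb2, Tha1, Etl4 and upstream of Alb held without each library in turn. Near Tspan5 the call ended without controls 1 or 2 (edgeR adjusted p = 0.138 and 0.179) or mutants 1, 2 or 3 (0.0835, 0.0616 and 0.0714). Near Schip1 it ended without controls 1 or 2 (edgeR adjusted p = 0.0879 and 0.111) or mutants 1 or 3 (0.0926 and 0.0529), and near Mboat1 without the same 4 (edgeR adjusted p = 0.129, 0.157, 0.135 and 0.104). Near Gm3646 it ended without control 1 or mutant 1 (edgeR adjusted p = 0.0578 and 0.0711). Those at Slc1a2 ended without control 1, mutant 1 or mutant 3 (edgeR adjusted p = 0.0791, 0.0510 and 0.0678), and at Lef1 without control 1 or mutant 1 (0.0745 and 0.0617). The Axin2 region at 108890860–108891915 lost its call without controls 1, 2 or 3 (edgeR adjusted p = 0.0934, 0.0610 and 0.0604), mutant 1 (0.111) or mutant 2 (0.0550). The one at 108896777–108897773 lost it without controls 1, 2 or 3 (edgeR adjusted p = 0.0934, 0.0542 and 0.0569), mutant 1 (0.0615) or mutant 3 (0.0795), and the Oat region without control 1 (edgeR adjusted p = 0.175), control 3 (0.0993), mutant 1 (0.0554), mutant 2 (0.0712) or mutant 3 (0.118).

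**Figure D5:**
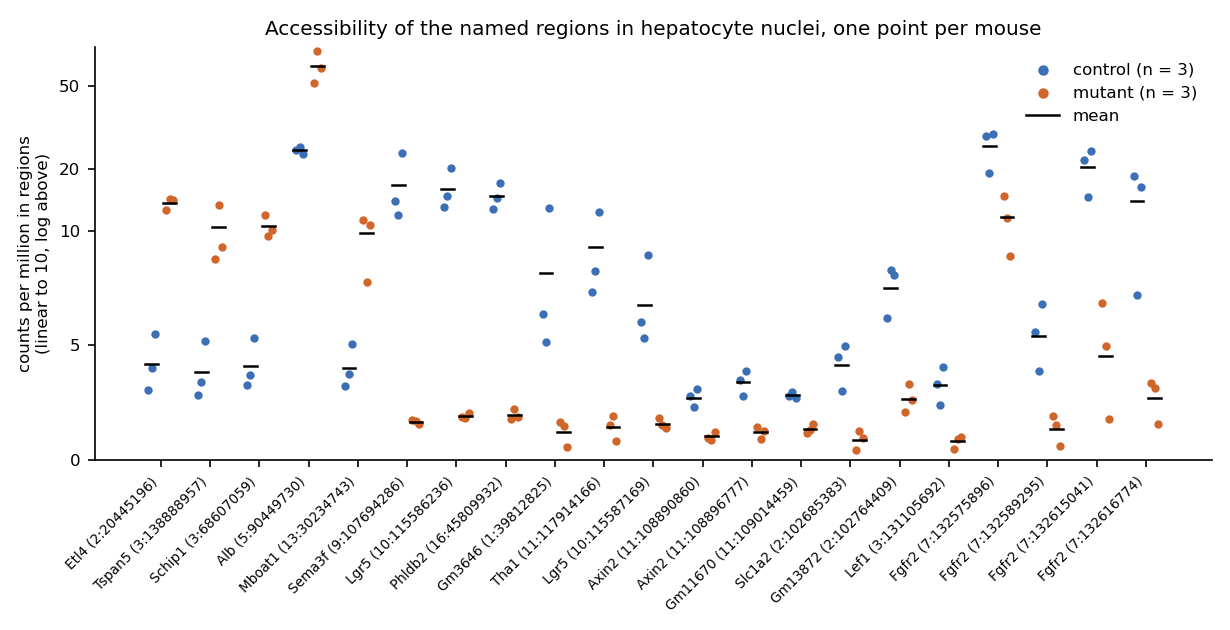
Accessibility of named regions in hepatocyte-like nuclei, in CPM on an axis that is linear to 10 and logarithmic above, with 1 point per liver for 3 controls and 3 mutants. The region 337 bp from the start of Lgr5 fell from 15.98 ± 3.71 to 1.91 ± 0.109 and the region upstream of Alb rose from 24.5 ± 0.940 to 62.6 ± 11.0 (mean ± SD).

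Accessibility also differed between the ends of the ranking. In controls the promoter region of Cyp2e1 (chromosome 7, 140763183–140764127) was more accessible at the pericentral end (log2 3.22, edgeR adjusted p = 2.66e-36) and that of Cyp2f2 (27119428–27120343) at the periportal end (−3.85, edgeR adjusted p = 3.7e-30). In mutants these were 2.26 and −1.74. Cyp2e1 and Cyp2f2 are scoring genes, so the ranking used their own transcripts and part of these differences may be built in. The start of Tcf7l1 (chromosome 6, 72788819–72789727) was −1.31 in controls and −0.04 in mutants, a region within Tcf7l2 (chromosome 19, 55780975–55781770) −1.38 and −0.61, and the region near Lef1 4.09 and 0.36. Of 91224 regions tested in controls, 10102 were more accessible at the pericentral and 8808 at the periportal end, against 3314 of either kind among 87192 in mutants, and the edgeR interaction test called 8110 of 88202. Of 17380 control-zonated regions tested in mutants 12439 kept the sign, and the median size went from 0.80 to 0.14. Of 3311 regions picked in mutants instead, a choice added later, 58.8% had the smaller difference in mutants, with medians of 0.79 in controls and 0.71 in mutants. Of the 310 falling regions 266 were pericentral in controls, where 31.9 would be expected, and part of this excess may also come from the shared controls. At an unadjusted p under 0.05, 42.1% of 4235 falling regions were pericentral. In 20 simulations of unchanged mutants, added after the overlap had been seen, the share was 11.9% to 19.8%, of 305 to 363 falling regions each. These were also drawn around the observed control means and cannot tell how much of the excess comes from the shared controls.

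Endothelial-like, macrophage-like and stellate-like nuclei, in which Albumin-Cre should leave Tcf7l2 intact, showed few changes, and these were transcripts that hepatocytes make. In endothelial-like nuclei 6 of 5685 genes fell and none rose in edgeR's test with BH adjustment, among them Mup11 (343 ± 115 to 4.66 ± 8.07 CPM), Cyp2c38 (82.2 ± 29.7 to 5.64 ± 3.35 CPM), Mup7 (125 ± 18.99 to 13.5 ± 10.6 CPM), Glul (161 ± 19.2 to 52.6 ± 5.01 CPM) and Cyp2e1 (757 ± 250 to 120 ± 73.1 CPM). In macrophage-like nuclei 3 of 3780 fell (Mup11, Cyp2c38 and Cyp2e1), and in stellate-like nuclei 2 of 8940 (Mup11 and Rnase4, whose transcripts overlap those of Ang). At an unadjusted p under 0.05 there were 368, 231 and 411 genes, and DESeq2 called 6, 10 and 15. The endothelial Wnt ligand Wnt2 (186 ± 67.2 and 150 ± 45.7 CPM, edgeR adjusted p = 0.816) and the R-spondin Rspo3 (132 ± 75.7 and 119 ± 35.8 CPM, edgeR adjusted p = 0.911) were not called. A cluster led by Wnt9b, Lhx6 and Selp (587 nuclei, 563 of them mixed) stayed unnamed and was left out of this test. So was a cluster of 203 nuclei with Gja5 and Vwf among its leading genes. In simulated endothelial sums edgeR recovered 26.1% of 2-fold changes, so changes of that size could be missed. The hepatocyte profile made up an estimated 37.3%, 24.3% and 49.5% of UMIs in endothelial-like nuclei of controls 1 to 3 and 27.2%, 28.2% and 13.8% in mutants 1 to 3. Without controls 1 to 3 and mutants 1 to 3 in turn, edgeR called 2, 3, 7, 1, 6 and 13 genes in endothelial-like, 25, 4, 3, 2, 6 and 4 in macrophage-like and 2, 6, 29, 2, 1 and 4 in stellate-like nuclei. Without controls 1, 2 and 3 and mutants 1 and 2 endothelial Glul lost its call (edgeR adjusted p = 0.181, 0.0592, 0.0631, 0.0842 and 0.0574), as did endothelial Cyp2e1 without controls 1, 2 and 3 and mutant 1 (edgeR adjusted p = 0.175, 0.0506, 0.0855 and 0.120). Endothelial Cyp2c38 lost it without control 2 (edgeR adjusted p = 0.0603) or mutant 1 (0.0645), and Mup7 without control 1 (0.104) or mutant 1 (0.0645). In macrophage-like nuclei Cyp2e1 lost it without control 3 (edgeR adjusted p = 0.0891) or mutant 1 (0.141), and in stellate-like nuclei Rnase4 without mutant 1, 2 or 3 (edgeR adjusted p = 0.0841, 0.140 and 0.0557).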

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

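The test for a loss of pericentral nuclei was chosen after the levels of some pericentral genes in mutants had been seen, and the genes that name the rare clusters were added after the clusters had been seen.

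Zonation differed between genotypes for 1623 genes and 8110 regions by the interaction test, and genes picked for zonation in controls mostly had differences nearer 0 in mutants (96.8%). Part of this may come from the choice of genes, since among genes picked in mutants the share was 65.0%. A loss of pericentral nuclei from the mutant samples is argued against as the whole cause, since 12 of 74 genes that would then fall by at least 1 on the log2 scale (16.2%) lay above the expected fall by more than 2 standard errors, and 7 of these 12 had fold changes above 0. A noisier ranking of mutant nuclei, some of whose scoring genes had themselves fallen, may account for part of the flattening and cannot be told apart from a flatter axis. Without any ranking, scores of pericentral and periportal genes of like level in both genotypes correlated across nuclei with −0.868 ± 0.00399 in controls and −0.499 ± 0.0400 in mutants (n = 3 each). This was weaker in mutants but short of the preset bound of less than 0.5 times the weakest control. The genes numbered 50 per end, more than the 45 and 40 of the fixed lists, so these data entered their choice. Part of the weaker correlation in mutants may come from that choice. The planned biological explanation, loss of TCF7L2 binding in hepatocytes, stays open beside the depth of nuclei at the 2 ends, whose order was the opposite in mutants and which was not tested.

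For splits of the 6 livers into other groups of 3, 10 in all, the splits are too few for a share under 0.05. The real split gave 1623 genes with changed zonation and the highest other 0, so 1 of the 10, the real one, gave as many. For zonation in controls, swapping the ends within livers gives 4 arrangements, again too few, with 2908 genes and 18910 regions for the real one and 0 for the highest other.

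A cluster led by pancreatic acinar genes (Cpb1, Pnliprp1, Prss2) held 27 nuclei, 25 of them from mutant 3 and 1 each from control 3 and mutant 1. In a cluster led by adipocyte genes (Plin1, Cfd, Adipoq), mutant 3 gave 12 of 20 nuclei. Of 72 nuclei in a cluster led by lymphatic genes (Mmrn1, Ccl21a), 40 were from mutant 3.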

How the results depend on the processing

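Alternatives chosen after the data had been seen were mixed nuclei kept, nuclei above 100000 UMIs left out, unnamed nuclei left out, peak counts read as fragments, and the mutants' own zonation from periportal scoring genes. No named result reversed. Of 1530 values of 102 named hepatocyte genes over 15 alternatives, 1420 kept their direction and side of the threshold, 41 lost a call, 50 gained one and 19 changed sign without being called. Direction and side were also kept by 196 of 200 values of named zonated genes, 230 of 240 of changed zonation, 242 of 354 of named regions and 57 of 80 of genes in other types. All 21 named regions lost their calls when a peak in at least 1 library of each group was enough. The 48 shares of nuclei with a UMI kept their direction. Total counts of calls, both directions together, that are not given below stayed within 1.5 times. In simulated hepatocyte sums edgeR found 8% of 2-fold changes, and the cause of this low share was not tested. The TCF/LEF motif test and its alternatives were not run, for lack of a genome sequence.

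DESeq2 gave 258 changed genes in hepatocyte-like nuclei, 207 over all nuclei, 10 in macrophage-like and 15 in stellate-like nuclei, 1717 changed regions, 1840 zonated genes and 994 genes with changed zonation. All 68 hepatocyte and 377 region calls were among DESeq2's, which made 38 false calls among 151 in simulated hepatocyte sums against edgeR's 6 among 90. With no filter on low counts there were 208 genes in hepatocyte-like nuclei and 109 over all nuclei, and the count over all kept nuclei was 42. Regions at an adjusted p under 0.01 numbered 76, and with a peak in at least 1 library of each group 0. Apart from the construction of these settings, the cause was not tested.

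The labels give both groups replicate numbers 1 to 3 but do not say that a number marks a shared day. Deviations of equally numbered hepatocyte sums correlated with −0.0573, 0.0202 and −0.464, and not every sample correlated best with its own number. Deviations among only 3 livers per group cannot show whether a number marks a shared day, so the pairing stays unknown. With the number as a replicate block there were 25 changed genes in hepatocyte-like nuclei (24 of the 68), 18 over all nuclei, 3 in endothelial-like and 18 in macrophage-like nuclei, and 95 changed regions (91 of the 377). In this fit the interferon list had adjusted p = 0.820 with the opposite direction and the clock list 0.0824. The fit spends degrees of freedom on the block.

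With an estimated correlation 5 lists were called, and 5 with fry. Adjusted p with the estimated correlation was 0.299 for periportal, gluconeogenesis, cholesterol, clock and immediate early genes, 0.419 for fatty acid oxidation, 0.473 for xenobiotic and 0.335 for female-biased genes. With fry it was 0.288 for periportal, 0.265 for gluconeogenesis and cholesterol, 0.376 for fatty acid oxidation, female-biased and immediate early genes, 0.411 for xenobiotic and 0.286 for clock genes.

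Without each library in turn, counts ranged from 24 to 79 in hepatocyte-like nuclei, 17 to 34 over all nuclei, 1 to 13 in endothelial-like, 2 to 25 in macrophage-like and 1 to 29 in stellate-like nuclei, and 103 to 373 for regions. Adjusted p of the lists ranged from 0.000143 to 0.177 (periportal), 0.0240 to 0.861 (bile acids), 0.0369 to 0.703 (fatty acid synthesis), 5.88e-07 to 0.0854 (fatty acid oxidation), 1.53e-06 to 0.490 (xenobiotic), 0.0205 to 0.904 (lipid transport), 0.377 to 0.868 (hepatocyte transcription factors), 0.00911 to 0.904 (interferon), 0.259 to 0.987 (fibrosis), 0.00385 to 0.357 (clock), 3.14e-05 to 0.564 (female-biased), 0.000274 to 0.396 (immediate early), 0.000759 to 0.564 (ER stress) and 0.393 to 0.815 (proliferation). Mutant minus control shares of nuclei ranged from −0.202 to 0.187 percentage points (B cell-like), −1.04 to 0.449 (endothelial-like) and −4.04 to 0.402 (hepatocyte-like). Each of these fits has 1 liver fewer, and beyond that the cause was not tested.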

Other observations

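Among the tests reported here, that of a common factor per gene was chosen after the values had been seen, the prediction for Alb transcripts was written after the rise of the region upstream of Alb had been seen, and the verdicts on free hepatocyte RNA were made stricter after its ratios had been seen.

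Zonation also changed for some members of gene groups outside the Wnt programme. Of 25 acute phase genes 10 had a higher and 2 a lower pericentral minus periportal difference in mutants, of 22 clock genes 7 and 1, of 22 fatty acid synthesis genes 5 and 1, of 30 fatty acid oxidation genes 0 and 9, and of 27 hepatocyte transcription factors 5 and 2 (edgeR's interaction test with BH adjustment). Of 24 male-biased genes 9 were pericentral and 8 periportal in controls, and 5 and 8 changed. Pdzrn3 went from a log2 difference of 5.42 in controls to 0.35 in mutants, Npr2, a receptor for natriuretic peptides, from 5.16 to 0.74, Nipal1, a magnesium transporter, from −3.95 to −0.03, and Rasgef1b from −3.54 to −0.55. Tbx3os1, which overlaps Tbx3 on the opposite strand, went from 6.84 to 1.87.

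The regions with the steepest zonation in controls included ones near Glul and in Slc1a2. Both are scoring genes, so part of the difference at these regions may be built into the ranking. A region on chromosome 1 (153855643–153856491, in Teddm2) had a log2 pericentral minus periportal difference of 6.22, and one at Slc1a2 (chromosome 2, 102705823–102706746) of 5.85. A region at Anks1b (chromosome 10, 90562655–90563576) was at −5.18 in controls and −2.46 in mutants, and one near Plxna2 (chromosome 1, 194472285–194473125) at −4.27 and −0.77. Outside hepatocytes, Tcf7l2 was at 1228 CPM in control and 1005 CPM in mutant macrophage-like nuclei and at 444 and 422 CPM in stellate-like nuclei.

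Hepatocyte transcripts were lower in other cell types of mutants, and free RNA from hepatocytes could be the source of some of them. Taking the fixed hepatocyte markers to set its level, observed UMIs of the called genes in controls had a median of 1.56 times the prediction, within 2 times for 5 of 11 genes and types, with ratios from 0.1301 for Cyp2c38 to 10.7 for Mup7. In mutants, a comparison added after the values had been seen, the ratios were 24.7 for Glul and 16.5 for Mup7 in endothelial-like nuclei. A single source with the make-up of nuclear RNA would not give a spread this wide. That make-up was assumed, which keeps free RNA open, and for Glul transcription in endothelial cells themselves stays open too. Free RNA of another make-up than nuclear RNA, for instance from cytoplasm, should give each gene a common factor across types. Over genes called in at least 2 types the highest ratio in controls was 1.28 times the lowest for Mup11, 1.15 for Cyp2e1 and 1.07 for Rnase4, but 4.33 for Cyp2c38 (0.1301 in endothelial-like and 0.563 in macrophage-like nuclei). Much of the gap for Cyp2c38 lay in control 1, with 17 UMIs against 94.4 predicted and 80 against 47.1. The ratios were 0.110 and 0.241 in control 2 and 0.163 and 0.305 in control 3. In mutants the ratios of Mup11 were 10.7, 4.73 and 10.6 in endothelial-like, macrophage-like and stellate-like nuclei, on 6, 1 and 9 UMIs. With 1 of 4 genes apart, this make-up stays open too.

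The region upstream of Alb was more accessible in mutants. Extra copies of this stretch within the Alb-Cre transgene are a candidate explanation. In keeping with that hypothesis, Alb transcripts did not rise with it, at 2744 ± 750 and 2210 ± 358 CPM (n = 3 each, log2 fold change −0.36). Reads from transgene copies were not told apart from those of the gene itself, and a change of the gene's own chromatin stays open.

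Splits of the 6 livers into other groups of 3 are too few for a share under 0.05, so only the values are given. Changed genes in hepatocyte-like nuclei numbered 68 in the real split and 2 in the highest other, over all nuclei 42 and 3, and changed regions 377 and 11. Called gene lists numbered 13 and 11. In endothelial-like nuclei the counts were 6 and 0, and in macrophage-like nuclei 3 and 1. In stellate-like nuclei 2 of the 10 splits gave as many calls as the real 2, the highest 7.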
